A study of Mus musculus with 12 samples.

How the data were processed

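RNA was measured in mixed cortex and hippocampus of adult male mice aged 3 to 5 months, either naive or 90 min after maximal electroconvulsive stimulation (MECS), a current of 85 mA for 1 s through ear clips that caused generalized convulsions. Per the labels' protocols, homogenized tissue was irradiated at 400 mJ/cm2 with ultraviolet light, which crosslinks RNA to protein, an input sample was taken from the lysate, and the rest was immunoprecipitated with an antibody against U1-70K, the protein of the U1 small nuclear ribonucleoprotein (U1 snRNP) that Snrnp70 encodes. The 12 libraries form 4 groups of 3: naive input, MECS input, naive U1 and MECS U1. None is a control precipitate, so a ratio of U1 to input cannot separate association with U1 from other differences in RNA recovery. Enriched or higher with U1 means here higher in the immunoprecipitate than in input. The labels' protocols name a strand-specific total RNA kit with depletion of ribosomal RNA and single-end reads of 100 bp. Libraries made with another antibody that the protocol mentions were not used here.

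The authors deposited 1 table of whole-number counts per library, with Ensembl gene identifiers and no normalization. Per the submitters' processing notes, which give no roles or order, Trimmomatic 0.39, FastQC, HISAT2 2.2.0, StringTie 2.1.3, Salmon 1.4 and DESeq2 were used with genome build mm10. The program that counted the reads, its strand setting and its annotation are not given in the sources used here. Each table holds 55471 identifiers, of which 55144 matched GENCODE release M21 (GRCm38, the same assembly as mm10) and 327 did not. Coordinates and overlaps are from that annotation. Rows of each table that name no gene were left out of library sizes and tests: reads in no gene made up 88.3 to 91.3% of each library's 42467790 to 129874136 listed reads, and 1.42 to 1.84% of reads, 704432 to 1962312 per library, were counted in genes.

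The counts lay mainly in genes whose exons overlap a gene on the other strand, so each annotated gene is called a feature here, and each feature was also described by the gene it lies under. A feature was given such a gene, called its host, where at least 50% of its exon bases lay inside exactly 1 opposite-strand gene and no more than 10% inside any other. It was classed as exon or intron where at least 80% of the overlap was exonic or intronic in the host, and otherwise as mixed. This gave 8064 features a host, 5704 hosts in all, holding 52.8 to 59.1% of each library's gene counts. Counts of features were summed per host and tested in the same way. The host analysis was chosen after seeing the data, and genes named as hosts were chosen after their values were seen. A value printed for a feature with no host cannot be assigned to a transcript: without the strand setting, reads of the gene itself, of an unannotated opposite-strand RNA and of readthrough from a neighbour cannot be separated.

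Groups were compared with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM size factors, the default filterByExpr filter and Benjamini-Hochberg adjustment at 0.05. Fold changes are on the log2 scale, and each standard error (SE) is the fold change divided by the square root of its F statistic. The 5 comparisons were MECS against naive in input and in U1 RNA, U1 against input in naive and in MECS brain, and the MECS effect on the ratio of U1 to input, an interaction over all 12 libraries. CPM are counts relative to the TMM-scaled sum of gene counts of a library, as edgeR's cpm function gives them. Alternatives were RLE or library size scaling, other filters, DESeq2 1.42.0, limma-voom (limma 3.58.1), removal of mitochondrial, ribosomal RNA and small RNA genes, all libraries in 1 fit, a replicate block and leaving out each library.

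Named features followed a fixed rule: past the threshold, log2 CPM of at least 2, groups that did not overlap (10% of unchanged features by chance), no predicted or clone symbols, and the 12 largest changes in each direction. Up to 4 members of each gene list with the smallest p, and Snrnp70, Khdrbs1, Homer1, Fos, Arc, Npas4 and Bdnf, were also eligible. Some features that met the rule are not reported here. The 34 gene lists, 623 symbols in all, were fixed as well. Lists with at least 3 measured members were tested with limma's camera, with a preset inter-gene correlation of 0.01 on log2 CPM with a prior count of 2, and alternatively with an estimated correlation or with fry. Ratios of U1 to input per animal used a pseudocount of 0.5 CPM and a mean of at least 1 CPM. Shares and ratios were compared with 2-sided exact permutation tests, for which the smallest p of 3 against 3 is 0.1.

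Title prefixes tie each U1 library to the input library of the same animal. Deviations from the group means correlated across tested features at 0.02, -0.10 and -0.02 between the paired naive libraries and at 0.11, 0.22 and 0.12 between the paired MECS libraries. Each MECS library correlated best with its own pair, whereas each naive pair fell below the highest value between different naive animals, 0.05, 0.07 and 0.07, so the values show the pairing in MECS but not in naive libraries. Because the pairs come from the same lysates, fits with the animal as a block were treated as paired fits. The labels do not say outright that replicates of a group are separate animals, so p-values measure the spread between these samples. No 2 libraries of a group agreed within counting noise, with chi-square per degree of freedom from 2.34 to 5.71.

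The tests were tested on simulated data, with counts drawn at the real means and library sizes and 100 features changed at each fold. For a 2-fold change, 55, 52, 39, 54 and 19% were recovered in the 5 comparisons in the order above, and for a 4-fold change 87, 89, 86, 90 and 82%. These simulations covered 10402, 11141, 10918, 10791 and 12184 features, and 4.05, 5.37, 8.76, 4.64 and 1.94% of their calls were unchanged features. Intervals of shares are 95% exact Clopper-Pearson intervals and cover counting error only.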

Results

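The series profiled RNA of mouse cortex and hippocampus, and the RNA bound to the U1 snRNP, with and without an electrically induced convulsion. U1 snRNP recognises 5′ splice sites and also restrains premature polyadenylation within introns, and the question was whether neuronal stimulation alters what it binds. There were 3 libraries in each of 4 groups. Gene counts per library ranged from 704432 (naive input 2) to 1962312 (naive U1 2). Between 20865 and 26166 features had a count, and 8567 to 12923 had at least 10.

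Some genes whose transcripts are abundant in brain had few counts. Actb, which encodes cytoplasmic actin, had 8 to 39 counts per library, and Snap25, a presynaptic membrane protein, had 8 to 22. Counts were higher for Camk2a, which has no opposite-strand gene, at 34 to 211, for Gapdh at 58 to 319, for Malat1 at 364 to 1689 and for mt-Nd5 at 163 to 4314. Grin1os, annotated opposite the NMDA receptor gene Grin1, had 2536 to 6889 counts. Ube3a, which lies opposite the long noncoding RNA gene Snhg14, had 5121 to 20472. Features lying under exons of an opposite-strand gene were 2.22% of all annotated features and held 25.1% of gene counts, and those under opposite-strand introns were 12.6% of features with 32.3% of counts. The 72.2% of features with no opposite-strand gene held 13.8%. Median counts per exon kb, summed over the 12 libraries, were 332 under opposite exons, 173 under opposite introns and 0.542 without an opposite-strand gene. The largest single share, 14.1% of gene counts, belonged to CT010467.1, a ribosomal RNA gene opposite Gm42418, and 2.30% belonged to Gm37376, opposite the nuclear RNA Malat1. Because the strand setting of the counting is not given in the sources used here, a value under a symbol below is that of the feature so annotated, not a measured level of that gene's transcript, and gene lists were read by the features' own symbols unless stated.

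**Figure D1:**
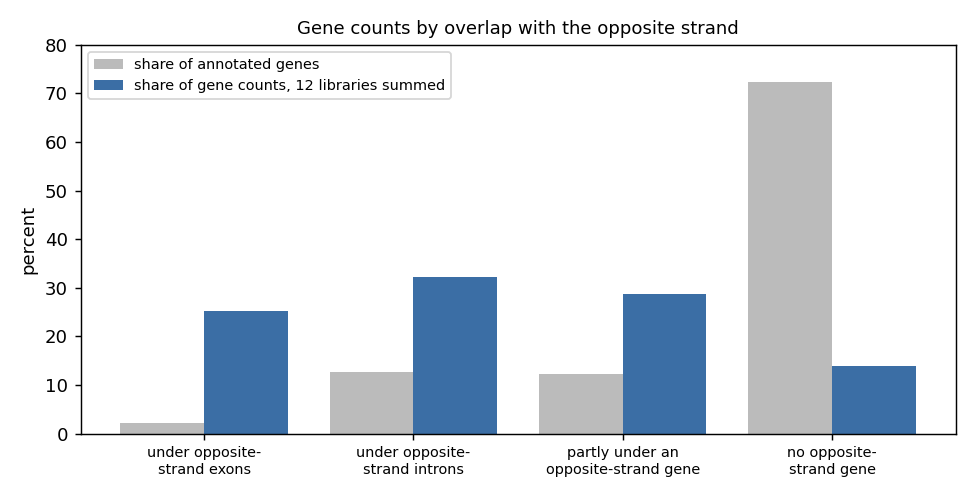
Percent of annotated features (grey) and percent of gene counts summed over the 12 libraries (blue) in 4 classes of overlap with a gene on the opposite strand. Features with no opposite-strand gene made up 72.2% of features and 13.8% of counts, whereas those under opposite-strand exons made up 2.22% and 25.1%.

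MECS against naive input RNA asked which RNAs changed 90 min after stimulation. Features inside Adamts9, which encodes a secreted metalloproteinase (chromosome 6, 92772699 to 92943492, minus strand), rose from 87.8 ± 8.42 to 222 ± 33.6 CPM (SD, n = 3 each), a log2 change of 1.34 (SE 0.17). Features inside Ppm1h, a protein phosphatase gene, rose from 121 ± 16.1 to 321 ± 105 CPM. The 1 feature inside Sorcs3, a neuronal sorting receptor gene (chromosome 19, 48206025 to 48805505, plus strand), rose from 21.7 ± 3.74 to 57.8 ± 22.6 CPM. The 1 feature inside Bmp6, a growth factor gene, rose from 2.8 ± 2.1 to 17.9 ± 7.5 CPM, by 2.52 (SE 0.53). The 1 feature of Cdkn1a, which encodes a cell cycle inhibitor, rose by 1.57 (SE 0.36). Smaller rises were found inside the amphiphysin gene Amph at 1.01 (SE 0.18), the potassium channel gene Kcnq1 at 1.21 (SE 0.19) and the histone deacetylase gene Hdac4 at 0.64 (SE 0.14). Of 3024 hosts tested, 24 rose and 10 fell. The 1 feature under the transcription factor gene Foxo1 fell by 0.71 (SE 0.17), and the 1 feature under Riox1 by 1.31 (SE 0.30).

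By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 53 of 10402 features rose and 10 fell, and 1005 had an unadjusted p under 0.05. Of the 53 that rose, 33 were intron features of a host, among 2772 tested, and none of those 2772 fell. Among features named by the fixed rule, the largest rises were at Ccdc103, a cilium gene (2.57, SE 0.47), Ube3b, a ubiquitin ligase gene (2.26, SE 0.40), and Hif1a, which lies in an intron of the noncoding gene Gm15283 (1.70, SE 0.24). Hif1a is the only feature of the host Gm15283, so both names stand for the same counts. The feature Kcnq1ot1, annotated on the antisense strand within introns of Kcnq1, rose by 1.33 (SE 0.20). It held most counts of the host Kcnq1, for example 70 of 81 in naive input 1 and 954 of 990 in MECS U1 1. Values of this host and this feature are therefore not separate results. Ncoa3 (1.09, SE 0.19) overlaps Sulf2, and Scrn1 (0.99, SE 0.20) overlaps Wipf3. Igsf11, Prpf38b, Rhbdd2, Aagab and mt-Nd6 rose by 1.24 to 1.59. Slc22a8, an organic anion transporter gene, fell by 1.84 (SE 0.43), and Rbm20 fell by 1.74 (SE 0.41). Mir3544, Zbtb2, Lca5, Il17rd, Ovca2, Vinac1 and Pgr fell by 0.76 to 1.53. Ube3b, Hif1a, Kcnq1ot1 and Ncoa3 kept their calls under each alternative run, and the other 17 of 21 features that met the naming rule each lost theirs under 1 or more. The count depended on single libraries: it was 19, 21 and 31 without naive input 1, 2 and 3, 24 without MECS input 3, and 114, of which 51 fell, without MECS input 1. It was 129 with library size scaling, 111 without a filter and 97 with a filter on CPM.

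Several classical activity genes could not be tested by their own symbols. Fos had 0 to 9 counts per library, Npas4 1 to 8, Bdnf 2 to 13 and Khdrbs1 1 to 6, too few to be tested. Homer1 (0.25, SE 0.29), Arc (0.04, SE 0.37) and Snrnp70 (0.26, SE 0.30) did not pass the test. By own symbols, 11 activity-induced transcription factor genes had a median of 0.01 and 5 activity-regulated synaptic effector genes a median of 0.15, with 0 called and adjusted p = 0.955 by camera for each. Of 22 gene lists, camera placed 3 past the threshold. Of the 14 measured intronless genes, 12 had a negative change, with a median of -0.39 and adjusted p = 0.00663. None passed over all genes and 1 did when adjusted over the list alone, Jund (-0.75, SE 0.22), whose features lie opposite Gm11175. All 7 measured mitochondrial mRNAs had a positive change (adjusted p = 0.0214), and 2 rose over all genes and 2 when adjusted over the list alone, mt-Nd6 and mt-Nd2 (0.87, SE 0.20). All 5 measured U1 snRNP protein genes had a positive change (adjusted p = 0.0214), and 0 rose over all genes and 1 when adjusted over the list alone, Luc7l3 (1.17, SE 0.34). With an estimated correlation, each of these lists had adjusted p = 0.982 by camera. When lists were read by host gene, an analysis chosen after seeing the data, 2 of 11 passed, with 4 of 4 measured activity-regulated synaptic effectors (adjusted p = 0.0158) and 3 of 3 measured glucocorticoid-response genes (adjusted p = 0.00894) above 0. The first held Sorcs3, which rose, and Inhba (1.52, SE 0.44), Bdnf (0.65, SE 0.40) and Nrn1 (0.25, SE 0.25), which did not pass over all genes. The second held Cdkn1a, which rose, and Fkbp5 (0.68, SE 0.22) and Hif3a (0.64, SE 0.25), which did not pass. Adjusted over the list alone, 2 and 3 of these hosts rose. With an estimated correlation, both lists had adjusted p = 0.456 by camera.

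MECS against naive U1 RNA asked how the immunoprecipitated RNA changed. Features inside Adamts9 rose from 142.5 ± 31.1 to 392.3 ± 85.6 CPM (SD, n = 3 each), a log2 change of 1.45 (SE 0.17). Those inside Ppm1h rose by 1.42 (SE 0.22), those inside Amph from 122 ± 36.6 to 327 ± 113 CPM, and the 1 feature inside Sorcs3 from 31.6 ± 14.7 to 82.1 ± 34.5 CPM. The 1 feature under Pcdh8, a protocadherin gene, rose by 1.20 (SE 0.25). The 1 feature inside Syn2, the gene of a synaptic vesicle protein, rose by 0.98 (SE 0.19). Of 3186 hosts tested, 16 rose and 3 fell, among them the host Sort1, a sorting receptor gene, whose 1 feature fell by 0.97 (SE 0.21). The hosts that rose in both input and U1 RNA were Adamts9, Amph, Gm15283, Hdac4, Itgad, Kcnq1, Pde10a, Ppm1h, Prkca and Sorcs3, 10 hosts where independent lists would share 0.129.

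**Figure D2:**
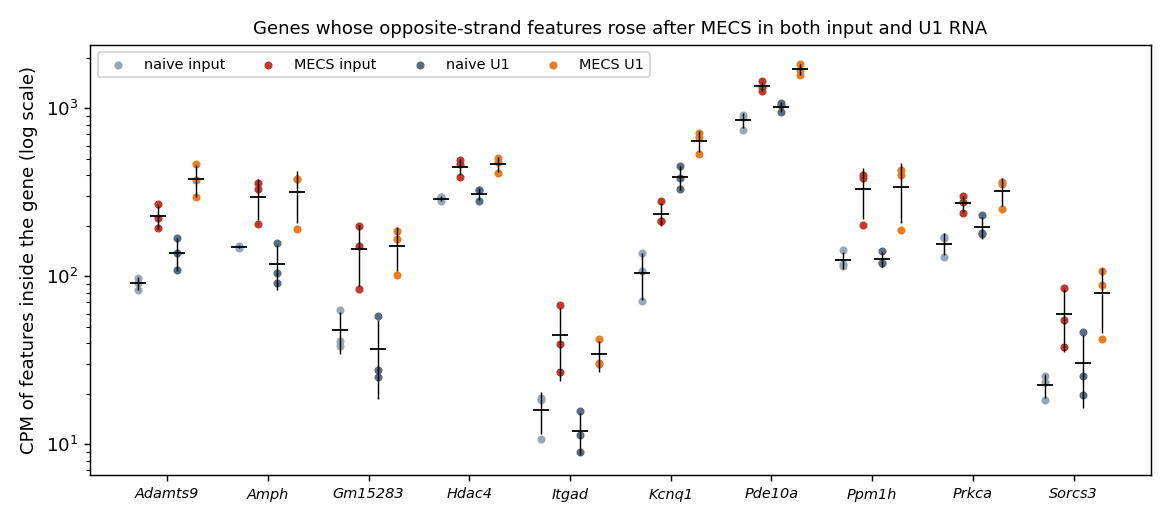
CPM on a log scale of features inside the 10 genes that rose after MECS in both input and U1 RNA, for each of the 12 libraries scaled together, with the mean and SD of each group of 3 as lines. For Adamts9 the naive input libraries lay between 83.2 and 98.4 CPM and the MECS input libraries between 194 and 269.

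By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 37 of 11141 features rose and 6 fell in U1 RNA, and 1172 had an unadjusted p under 0.05. Of the 37, 22 were intron features of a host. Ube3b showed the largest rise of the named features, from 5.19 ± 4.37 to 53.7 ± 15.0 CPM (SD, n = 3 each), followed by Tmem222 (3.01, SE 0.52), Hif1a in an intron of Gm15283 (39.0 ± 20.4 to 166 ± 48.8 CPM), Nespas opposite the imprinted gene Gnas (1.96, SE 0.35) and Ccdc103 (1.77, SE 0.38). Ccdc107, which overlaps Rmrp, the RNA of a ribonuclease, rose by 1.03 (SE 0.18). Ccdc152 overlaps Selenop, Ppp2r1b overlaps Sik2, Serpind1 lies in introns of Pi4ka and Ap3m1 overlaps Vcl, and these rose by 0.84 to 0.96. Fam187a and Rhbdd2 rose by 1.42 (SE 0.31) and 1.38 (SE 0.28). Slc22a8 fell by 2.08 (SE 0.40), Lca5 by 1.23 (SE 0.19), Irf1 by 1.12 (SE 0.20), Vinac1 by 0.98 (SE 0.17) and Engase by 0.74 (SE 0.15). Ube3b, Tmem222, Hif1a, Lca5 and Ppp2r1b kept their calls under each alternative run, and the other 12 of 17 each lost theirs under 1 or more. Among 9997 features tested in both kinds of RNA, 21 rose in both, where 0.191 would be shared by independent lists, and 3 fell in both. Input and U1 libraries came from the same animals, so these are not independent samples of animals.

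The count in U1 RNA was 15 without naive U1 1, 225 without naive U1 2, 13 without MECS U1 1 and 121 without MECS U1 2. DESeq2 called 86, the fit over all 12 libraries 88, and the fits without a filter and with a CPM filter 151 and 92. Homer1 (0.05, SE 0.27), Arc (0.17, SE 0.40) and Snrnp70 (-0.37, SE 0.26) did not pass. None of 24 lists passed camera at an adjusted p of 0.05, and fry and the estimated correlation also gave 0, although 4 lists had an unadjusted camera p under 0.05: long neuronal genes, mitochondrial mRNAs, pericytes and smooth muscle, and postsynaptic genes. By host gene, 4 of 11 lists passed, all upward. The activity-regulated synaptic effectors had 4 of 4 members above 0 (adjusted p = 0.00195), glucocorticoid-response genes 3 of 3 (adjusted p = 0.0300), ion channels 8 of 11 (adjusted p = 0.0254) and splicing regulators 9 of 12 (adjusted p = 0.0300). Over all genes 1 member, Sorcs3, rose, and adjusted over the list alone 3, 2, 3 and 4 members rose. Examples that did not pass over all genes were Bdnf (1.36, SE 0.39) and the splicing factor genes Tra2a (0.75, SE 0.17) and Srrm4 (0.57, SE 0.15). With an estimated correlation, all 4 lists had adjusted p = 0.583 by camera.

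U1 against input in naive brain asked which RNAs were enriched in the U1 immunoprecipitate over input. The 1 feature under Tagln, a smooth muscle actin-binding protein gene (chromosome 9, 45929619 to 45936058, minus strand), rose from 149 ± 44.8 to 1062 ± 432 CPM (SD, n = 3 each). The 2 features inside Mylk, the myosin light chain kinase gene, rose from 59.4 ± 8.97 to 298 ± 90.5 CPM. Pln, Notch3 and Nos3, the genes of phospholamban, a receptor of vascular smooth muscle and endothelial nitric oxide synthase, had 1 feature each. These rose by 2.39 (SE 0.23), 1.80 (SE 0.21) and 1.66 (SE 0.19). The 1 feature under Syp, the synaptophysin gene (chromosome X, 7638471 to 7653256, plus strand), fell from 3903 ± 914 to 680 ± 91.0 CPM. Slc32a1, the vesicular GABA transporter gene, and Slc1a2, the astrocytic glutamate transporter gene, also had 1 feature each. These fell by 2.37 (SE 0.22) and 2.16 (SE 0.17).

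By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 458 of 10918 features were higher in naive U1 RNA and 683 lower, 40.1% higher, and 2324 had an unadjusted p under 0.05. With library size scaling the split was 565 higher and 562 lower, 50.1% higher. Intron features of a host were higher in 146 and lower in 60 of 2871 cases, and exon features higher in 11 and lower in 105 of 422. At host level, 193 of 3099 were higher and 317 lower. The named features with the largest enrichment were Vamp8 (2.80, SE 0.49), the vascular connexin gene Gja4 (2.76, SE 0.49), Nans opposite Trim14 (2.65, SE 0.53), Nthl1 (2.45, SE 0.33) and Bvht (2.44, SE 0.28), a noncoding RNA gene. Med29, Cmss1, the smooth muscle myosin gene Myh11, Bcas3, the pericyte gene Rgs5, Hrh2 and Slc51b were higher by 2.33 to 2.43. Ccdc107, which overlaps Rmrp, had the largest fall, from 1529 ± 379 to 102 ± 31.2 CPM (SD, n = 3 each). Pter, Nop9, Pcsk1n, Aldoc, Nme7, Zmat5, Slc8a2 and the mitochondrial features mt-Ts1, mt-Nd1, mt-Ty and mt-Nd5 fell by 2.48 to 3.35. Without naive input 1, the count of called features was 711. Bcas3 and Rgs5 each lost their call with 1 library left out. Homer1 (-0.33, SE 0.31), Arc (-0.87, SE 0.43) and Snrnp70 (0.74, SE 0.29) did not pass.

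In naive brain camera placed 6 of 23 lists past the threshold. All 7 measured mitochondrial mRNAs fell over all genes and when adjusted over the list alone (list adjusted p = 2.3e-10), for example mt-Nd1 by 3.13 (SE 0.25) and mt-Co1 by 2.41 (SE 0.19). Of 5 oligodendrocyte genes, 3 fell by both counts (list adjusted p = 0.00200), among them Mbp by 2.13 (SE 0.25) and Mobp by 1.81 (SE 0.33). Of 18 presynaptic genes, 2 fell by both counts (list adjusted p = 0.0139), the active zone genes Bsn by 1.70 (SE 0.24) and Pclo by 1.04 (SE 0.30). Of 21 postsynaptic genes, 2 fell over all genes and 3 when adjusted over the list alone (list adjusted p = 0.0178), among them the kinase gene Camk2a by 1.80 (SE 0.29) and Shank1 by 1.22 (SE 0.23). Of 10 nuclear long noncoding RNA genes, 2 rose and 1 fell over all genes, and 7 rose and 1 fell when adjusted over the list alone (list adjusted p = 0.0178). The feature Kcnq1ot1, within introns of Kcnq1, rose by 2.01 (SE 0.20), and Snhg14, which overlaps Ube3a, fell by 0.79 (SE 0.18). Of 4 pericyte and smooth muscle genes, 2 rose over all genes, Myh11 (2.39, SE 0.49) and Rgs5 (2.36, SE 0.56), and 3 when adjusted over the list alone (list adjusted p = 0.00554), whereas the feature Tagln itself did not pass (0.21, SE 0.20). With an estimated correlation none of the 6 passed camera: adjusted p = 0.432 for mitochondrial mRNAs, 0.428 for oligodendrocytes, 0.450 for pericytes and smooth muscle and 0.661 for the other 3. By host gene, 0 of 11 lists passed camera.

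U1 against input in MECS brain asked the same of stimulated animals. The 1 feature under Tagln rose from 164 ± 45.6 to 853 ± 260 CPM (SD, n = 3 each). The 2 features inside Mylk rose by 1.73 (SE 0.19). The 1 feature each of Pln, Notch3 and Nos3 rose by 1.92 (SE 0.22), 1.80 (SE 0.18) and 1.66 (SE 0.19). The 1 feature under Syp fell from 3687 ± 1196 to 769 ± 177 CPM, and the 1 feature each of Slc32a1 and Slc1a2 fell by 1.82 (SE 0.21) and 1.64 (SE 0.15). The feature Tagln itself did not pass (-0.00, SE 0.19). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 356 of 10791 features were higher and 562 lower, and 2143 had an unadjusted p under 0.05. With the animal as a block, 1488 were called, 647 higher and 841 lower. Among 10232 features tested in both states, 234 were higher in both naive and MECS brain and 442 lower in both, where independent lists would share 14.4 and 36.6.

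The named features most enriched after MECS were Clec1b (2.93, SE 0.63), Gja4 (2.79, SE 0.53), Ybx2 (2.66, SE 0.65), Lao1 (2.52, SE 0.49) and Cox4i2 (2.45, SE 0.64). The transcription factor genes Gata2 and Tbx3, with Etnk2, Rtp3, Prr29, B3gnt3 and Tmem222, were higher by 2.03 to 2.23. Among the largest falls were those at the mitochondrial features mt-Tp (-4.19, SE 0.58), mt-Nd1 (-2.96, SE 0.23), mt-Ty (-2.90, SE 0.40) and mt-Nd5 (-2.75, SE 0.19) and at the astrocyte gene Aldoc (-2.88, SE 0.51). mt-Ts1, mt-Tq, mt-Nd2, Pcsk1n, Abhd17a and the axonal genes Epha5 and Basp1 fell by 2.42 to 2.78. Ybx2, Cox4i2 and Abhd17a each lost their call when single libraries were left out. Homer1 (-0.54, SE 0.26), Arc (-0.74, SE 0.34) and Snrnp70 (0.10, SE 0.26) did not pass.

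In MECS brain camera placed 6 of 23 lists past the threshold, all downward. All 7 mitochondrial mRNAs fell over all genes and when adjusted over the list alone (list adjusted p = 3.1e-10). Of 21 postsynaptic genes 5 fell over all genes, among them Camk2a by 2.07 (SE 0.21), and 6 when adjusted over the list alone (list adjusted p = 1.1e-06). Of 18 presynaptic genes 3 fell, Bsn by 1.68 (SE 0.16), Cplx1 by 2.38 (SE 0.42) and Pclo by 1.20 (SE 0.26), and 6 when adjusted over the list alone (list adjusted p = 0.000461). Of 18 ion channel genes 1 fell, Kcna2 by 1.45 (SE 0.38), and 6 when adjusted over the list alone (list adjusted p = 0.000677). Of 5 oligodendrocyte genes 3 fell by both counts (list adjusted p = 0.00200), and of 5 astrocyte genes 2 fell, Aldoc and Slc1a2, and 3 when adjusted over the list alone (list adjusted p = 0.00356). With an estimated correlation none passed camera, with adjusted p = 0.284 for mitochondrial mRNAs, postsynaptic genes, oligodendrocytes and astrocytes and adjusted p = 0.319 for presynaptic genes and ion channels. With the animal as a block, a further list, long neuronal genes, passed downward (adjusted p = 0.0342, against 0.0536 without the block and adjusted p = 0.293 with an estimated correlation). Read by host gene, 23 of 31 members of that list lay above 0, with a median of 0.14 (camera adjusted p = 0.372). The pericyte and smooth muscle list did not pass camera in MECS brain (adjusted p = 0.308), with a median of 0.02 over 3 measured members, of which Myh11 rose by 1.71 (SE 0.43). By fry the list had adjusted p = 0.0145. By host gene, 0 of 12 lists passed camera.

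The MECS effect on the ratio of U1 to input asked whether association with U1 changed beyond the RNA level. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 0 of 12184 features passed, and DESeq2 and limma-voom also called 0. An unadjusted p under 0.05 was found for 383 features, fewer than the 609 that chance alone would give. In simulation 19% of 2-fold changes were recovered for this comparison, so the absence of calls does not exclude changes of that size. The smallest adjusted p, 0.122, belonged to Ccdc107, which overlaps Rmrp, with a log2 change of 1.75. With the animal as a block it passed as the 1 feature called, at 1.88 (SE 0.30). It was likewise the 1 feature called with library size scaling, without a filter, with a CPM filter, and without naive input 3, MECS input 1 or naive U1 3. At host level, 0 of 3299 hosts passed by edgeR, and 109 had an unadjusted p under 0.05. Of 24 lists, camera placed 1 past the threshold, the nuclear long noncoding RNA genes, of which 9 of 10 measured members lay below 0 with a median of -0.54 (adjusted p = 0.0335, and adjusted p = 0.613 with an estimated correlation). None of its members passed, over all genes or adjusted over the list alone, for example Rian (-0.88, SE 0.41) and Meg3 (-0.59, SE 0.29). The pericyte and smooth muscle list did not pass (adjusted p = 0.0674), with 0 of 5 members above 0 and a median of -0.67. Nor did the U1 snRNP protein list (camera adjusted p = 0.0674, and 0.613 with an estimated correlation), with 0 of 6 members above 0 and a median of -0.64.

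The ratio of U1 to input was compared between features over exons and over introns of their hosts. The median log2 ratio of 4121 intron features was 0.10 ± 0.25 in naive and 0.11 ± 0.06 in MECS animals (SD, n = 3 each), and that of 543 exon features was -0.26 ± 0.24 and -0.15 ± 0.11. Intron features lay above exon features by 0.35 ± 0.20 in naive and 0.26 ± 0.15 in MECS animals, in 6 of 6 animals (2-sided exact sign-flip permutation p = 0.0313). The difference did not separate MECS from naive animals (exact permutation p = 0.5). By annotated span of protein-coding features, the difference of those over 100 kb minus those under 10 kb was -0.05 ± 0.23 in naive and -0.11 ± 0.10 in MECS animals, above 0 in 2 of 6 animals (exact sign-flip permutation p = 0.281), and MECS and naive animals were not separated (exact permutation p = 0.8). For intron features, hosts over 100 kb exceeded hosts under 30 kb by 0.10 ± 0.12 and 0.11 ± 0.07, in 5 of 6 animals (exact sign-flip permutation p = 0.0625).

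**Figure D3:**
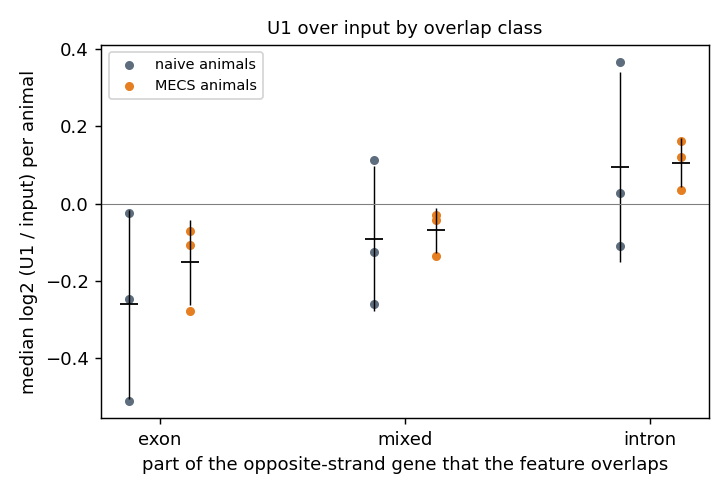
Median log2 ratio of U1 to input CPM per animal for features over exons, mixed parts or introns of an opposite-strand gene, with 1 point per animal and the mean and SD of 3 naive (grey) and 3 MECS (orange) animals as lines. Intron features lie above exon features in 6 of 6 animals.

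Ribosomal RNA features made up 14.7 ± 0.924% of gene counts in naive input and 8.44 ± 2.92% in MECS input (SD, n = 3 each, exact permutation p = 0.1), and 18.0 ± 2.13% and 14.7 ± 2.16% in U1 RNA (exact permutation p = 0.2). The lowest library, MECS input 3, had 6.08% (exact Clopper-Pearson interval 6.04 to 6.13%). Mitochondrial features fell short in the immunoprecipitate, with 0.412 ± 0.0523% in naive input and 0.0800 ± 0.0400% in naive U1 RNA, and 0.574 ± 0.146% and 0.111 ± 0.0348% after MECS (exact permutation p = 0.1 for each). Long noncoding RNA features held 35.4 ± 0.497% in naive and 39.5 ± 1.47% in MECS input (exact permutation p = 0.1), and 41.8 and 43.4% once mitochondrial and ribosomal RNA features were left out of the total. Protein-coding features held 43.9 ± 1.02 and 45.6 ± 1.30% in naive and MECS input (exact permutation p = 0.3), and the order turned to 51.3 and 49.6% (exact permutation p = 0.1) without those features. Small RNA features held 1.08 to 1.19% and the 10 most abundant features 15.5 to 22.5% of counts as group means. None of these comparisons can reach p under 0.1.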

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

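The tests of strand, genomic DNA and antisense transcription, that of a general intron shift and the splits of the libraries were chosen after the result was seen, as were the requirements that the striatal interval exclude 0 and that the intervals for GC content, intron position and the intron shift lie wholly above 0.3; the other tests were written before their results. The cell type lists were prompted by the vascular enrichment after it was seen, but were written before any value of their 85 vascular genes had been looked at.

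Counts of identifiers that did not match the annotation, which enter no named result, made up 0.0989% of gene counts in naive U1 libraries against 0.0858% in naive input, a small excess in a signal outside the main measurement. In MECS brain the shares were 0.0902 ± 0.0024% and 0.0885 ± 0.0055% (SD, n = 3 each).

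Counts concentrated in features that lie opposite another gene. Genomic DNA would give features under introns and features without an opposite-strand gene like counts per kb, but the ratio was 319.73 over all features and 10.8 over protein-coding features, the latter close to the bound of 10 set for excluding it. Antisense transcription counted on the annotated strand would leave ordinary genes abundant, but 77 ribosomal protein genes had a median of 5.00 CPM in input. Reads of a strand-specific kit counted on the strand opposite to the transcripts may account for the pattern: protein-coding features under opposite exons had 86.2 times the median counts per exon kb of those without an opposite-strand gene. The source of the few counts in features without an opposite-strand gene was not tested and stays open.

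Features inside vascular genes were higher in the U1 immunoprecipitate than in input in naive brain, with a median log2 ratio of 0.96 and 10 of 11 measured hosts of an 85-gene list above 0. Their difference from other hosts was 0.92 (interval 0.32 to 1.14, permutation p = 0.0001, the smallest the resamples can give, adjusted p = 0.00200). The permutation and the interval resampled hosts, not animals, so they do not measure the spread between animals. Among hosts with intron features Slc2a1 (1.78), Ets1 (1.56) and Col4a2 (0.96) led. In MECS brain the difference was 0.79 (interval 0.17 to 1.11, 11 of 11 hosts above 0, permutation p = 0.0001, adjusted p = 0.00200). The values argue against GC content as the whole cause, since the median was 0.909 (interval 0.32 to 1.17) after its trend was removed. A lower share of neuronal RNA would raise other non-neuronal types alike. Intron hosts of astrocyte genes (3 of 28 listed), the lowest list, lay 1.13 below the vascular difference, at -0.51 against other intron hosts (interval -0.56 to -0.35). Oligodendrocyte, microglial and neuronal hosts lay at -0.49, 0.29 and 0.04. The astrocyte and oligodendrocyte values go against a like rise of all non-neuronal types, but 3 and 4 hosts are too few to settle it. The microglial interval, -0.34 to 0.44 over 3 hosts, overlaps the vascular one. Intron position alone would put vascular intron hosts level with other intron hosts. Over 8 vascular intron hosts in naive brain the median was 0.715, against 0.098 for the others. The excess was 0.617 (interval 0.02 to 1.46, permutation p = 0.0014, adjusted p = 0.015). In MECS brain it was 0.494 (interval 0.12 to 1.12, permutation p = 0.0015, adjusted p = 0.015). These values argue against intron position as the whole cause for these 8 hosts. Both intervals reach below the bound of 0.3 set for excluding it, so a part played by intron position stays open. No biological explanation of this pattern was tested.

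Among 3 measured intron hosts of the activity lists, Sorcs3 rose after MECS in input, whereas Inhba (1.52, SE 0.44) and Nrn1 (0.25, SE 0.25) did not pass edgeR's test, and the synaptic effector list read by host gene was not past the threshold of camera with an estimated correlation (adjusted p = 0.456 in input and 0.583 in U1 RNA). A general shift of intron reads cannot be told apart from the pattern with 3 hosts. In U1 RNA, by their intron features, the 3 hosts exceeded 2233 other intron hosts, whose median was 0.08, by 1.435 (interval 0.40 to 1.73). That interval lies above the bound of 0.3 set for excluding a shift, but it spans only about the lowest to the highest host. By intron feature, Inhba and Nrn1 did not pass edgeR's test in U1 RNA either (adjusted p = 0.124 and 0.470). In input the 3 hosts exceeded 2083 others, whose median was 0.06, by 1.404. The interval there, 0.22 to 1.51, reaches below that bound. Striatal tissue in the MECS dissections cannot be told apart either. The median change of 3 striatal features in input was 0.3904, above the 0.3 set beforehand as the mark of striatal tissue. Its interval was -0.01 to 0.93, and 2 of the features lie at the Ppp1r1b locus. The hosts Pde10a and Sv2c, which rose in input from 819 to 1321 and from 10.7 to 32.7 CPM, were not in the striatal list. They were not weighed in this test. Transcriptional induction by the convulsion is the difference the design names; it stays open, as a hypothesis.

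The 10 splits of 6 libraries into 3 and 3 cannot give a share under 0.05. The other splits mix the real groups, so a real difference adds to the spread within each group and lowers their counts. These counts therefore do not show how many calls noise alone would give. MECS against naive input gave 63 features in the real split and at most 5 in the others, MECS against naive U1 gave 43 and at most 13, U1 against input gave 1141 and at most 0 in naive and 918 and at most 0 in MECS brain, and 1 split, the real one, reached each of these values. For U1 against input, the other 3 splits that part all 3 animals were among those with 0 calls by edgeR, with 199 to 523 features at an unadjusted p under 0.05 in naive brain and 177 to 229 in MECS brain. For the MECS effect on the ratio of U1 to input, all 10 splits gave 0 features by edgeR, with 383 at an unadjusted p under 0.05 in the real split and at most 578 in the others.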

How the results depend on the processing

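The alternatives were chosen before the data were examined, except those that use host genes or only features with a host, which were chosen after the result was seen. Of 131 alternative values of main results, 77 stayed within 1.5 times the call count or 1 SD of the difference, and 54 moved. Direction was not part of this rule. The MECS minus naive difference by gene length, -0.068, became 0.017 for intron features by host span and counted as kept. So did U1 against input in naive brain with library size only, with 565 higher and 562 lower against 458 and 683. Of 1268 alternative values for named features, 1158 kept their call, 110 kept only their direction and 0 reversed. Named calls held under each alternative run for 4 of 21 features in input and 5 of 17 in U1 RNA after MECS, and for 22 of 24 and 21 of 24 in naive and MECS brain for U1 against input. The cause was not tested unless stated.

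MECS against naive input called 129 with library size only, 111 with no filter, 97 with a CPM filter, 34 and 23 by host gene (at least 50 or 90% of exon bases; fewer units tested), and 19 to 114 with 1 library left out. MECS against naive U1 called 151, 92, 86 and 88 with no filter, a CPM filter, DESeq2 and all 12 libraries, 19 and 14 by host gene, 27 over features with a host, and 13 to 225 with 1 library left out. U1 against input called 510, 355 and 548 in naive and 352, 256 and 381 in MECS brain by host gene (both bounds) and over features with a host, and 711 to 1254 and 613 to 894 with 1 library left out. The MECS effect on U1 over input called 1 with library size only, no filter, a CPM filter and the replicate block, and 0 to 1 with 1 library left out; the 1 feature was Ccdc107 in each.

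The replicate block moved U1 against input in MECS brain to 1488 calls and the interaction to 1, added the long neuronal gene list in MECS brain and changed no other call of these paired results past these bounds. MECS and naive animals share only a number: same-number correlations were 0.07, -0.03 and -0.00 in input and 0.01, -0.01 and -0.10 in U1 RNA, not every library correlated best with its own number, and that block gave 142 and 35 calls.

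List calls went to 0 with an estimated correlation in input after MECS, in naive and MECS brain and in the interaction, and to 0 with fry in input after MECS and the interaction. By host gene they were 4 in U1 RNA after MECS and 0 in naive brain, MECS brain and the interaction. Without mitochondrial and ribosomal RNA features in the total, differences in percentage points for input after MECS were 0.0223 for small RNA, 1.66 for long noncoding and -1.75 for protein-coding features; for U1 against input in MECS brain they were 0.0858, -0.488 and -0.475, and in naive brain -0.0870 for protein-coding features. At the depth of these libraries, 19% of simulated 2-fold changes were recovered for the interaction.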

Other observations

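The test of host length and that of position within hosts were written before their results; the values per gene in the next paragraph were chosen after the result was seen.

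Beyond the vascular genes above, features inside Kcnq1, whose counts are mostly those of Kcnq1ot1, were higher with U1 by 1.92 (SE 0.19) in naive and 1.46 (SE 0.15) in MECS brain, and rose after MECS in both kinds of RNA. In naive brain the 1 feature inside the transcription factor gene Ebf1 was higher with U1, from 30.2 ± 9.43 to 123 ± 53.1 CPM (SD, n = 3 each). The 1 feature inside the endothelial gene Fgd5 was higher there by a log2 change of 2.07 (SE 0.28). The 1 feature inside Bmp6, which rose after MECS in input, was also higher with U1 in naive brain by 2.97 (SE 0.45), from 2.8 ± 2.1 to 24.9 ± 1.8 CPM. Its change after MECS in U1 RNA, 0.70 (SE 0.29), did not pass edgeR's quasi-likelihood test (adjusted p = 0.293 after Benjamini-Hochberg adjustment). Both rises were measured against the same naive input libraries, so low values there by chance would give both.

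Shorter transcripts after MECS, as increased polyadenylation within introns would give, should raise reads at the 5′ end of hosts more than at the 3′ end. Over 438 hosts with at least 2 intron features, the 5′-most minus the 3′-most change in input was instead -0.0553 on average (interval -0.10 to -0.01, sign-flip permutation p = 0.0098), with 191 hosts above 0, and the library values were -0.04 ± 0.02 in naive and -0.09 ± 0.01 in MECS input (SD, n = 3 each, exact permutation p = 0.1). The rule written beforehand for rejecting the prediction named only p of 0.05 or more and did not provide for a difference of the opposite sign, so reading this as against the prediction was decided after the result was seen. Fewer reads from the far end of long hosts had been predicted to lower the median change of hosts over 100 kb. These hosts instead changed by 0.0740 more than hosts under 100 kb (interval 0.04 to 0.11, permutation p = 0.0002, libraries exact permutation p = 0.2). This test used all intron features of a host without their position, so it does not show what happened at the far end. Hosts are not independent replicates, and these features cover few positions of each gene, so a shortening in particular genes may have been missed.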
